A study of Homo sapiens with 12 samples.

How the data were processed

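Poly(A) RNA was sequenced from RBE cells, an established human cholangiocarcinoma line, in 12 libraries that fall into 4 groups of 3. Per the labels, cells were kept for 22 days in vehicle (DMSO) or in 5 µM AG-120, then for 72 hours without or with 5 µM Nutlin. AG-120 (ivosidenib) inhibits mutant IDH1 and blocks production of 2-hydroxyglutarate (2-HG). Nutlin inhibits MDM2 and so activates p53. The groups are named vehicle, vehicle_Nutlin, AG120 and AG120_Nutlin. The labels give paired reads of 150 bases from poly(A)-selected libraries made and sequenced by a service company. They do not say whether the replicates of a group are separate cultures, so the p-values measure the spread between samples, which may be technical in part.

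The deposited table holds raw read counts per gene symbol, with no normalization. The processing notes name Partek, STAR, HTSeq and DESeq2 and the genome build hg19, without versions and without saying which of them made the counts. The values were whole numbers that summed to a different total in each library. The table had 55773 gene entries, of which 29603 held a count in any library. Of these entries, 28 carried a symbol that a spreadsheet had turned into a date, and 2 such symbols stood for 2 entries each. All were kept in the tests, and none is named. Gene positions are hg19 and were taken from the same table. The deposited stop lies 1 base past the last base of a gene, tested on 6 mitochondrial reading frames, so 1 was subtracted from it. Entries of 1 symbol can join several loci and can span more than any gene. None of those is placed on the genome in the text.

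Library totals ran from 16840161 to 27499433 counts, with a median of 19221201. Intervals and floors built on counts cover counting error only, since reads without molecular identifiers are not independent molecules. Where every library of a group held 0 counts, a fold is a lower bound against a floor of 3 counts over the group.

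Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr on the 4 groups, which left 15691, and libraries were scaled by trimmed mean of M values (TMM). One edgeR quasi-likelihood model (glmQLFit, with a term per group) was fitted to all 12 libraries. The comparisons were tested with glmQLFTest: the Nutlin response in vehicle cells, the Nutlin response in AG-120 cells, the AG-120 effect without Nutlin, the AG-120 effect with Nutlin, and the difference between the Nutlin responses, which is the interaction term. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p of at most 0.05. Levels are TMM-scaled CPM, given as mean ± SD with n = 3, and changes are log2 fold changes from the model.

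The tests, 37 gene lists, the rule for naming genes and the first set of alternatives below were fixed before the data were examined. The lists were written from general knowledge of each pathway. They cover p53 targets (6 lists by function: feedback regulators, arrest, apoptosis, DNA repair, metabolic and other targets, and their union without TP73, MDM4 and PTPRV), G1/S and G2/M genes, replication-dependent histones, type I interferon, antigen presentation and secretory inflammatory genes. Others hold biliary, hepatocyte, mesenchymal and epithelial junction genes, cholesterol and fatty acid synthesis, ATF4, unfolded protein, hypoxia and glycolysis, NRF2 and xenobiotic response genes. Further lists hold IDH and 2-HG metabolism genes, 2-oxoglutarate dioxygenase genes, germline genes, MAPK output genes, YAP and TGF-beta targets, ribosome biogenesis, and lysosome and autophagy genes. The last lists hold ribosomal protein, mitochondrially encoded and housekeeping genes, and markers of fibroblasts, endothelium and leukocytes. The 34 lists with at least 5 tested members were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 34 lists within each comparison. The same test with an estimated correlation is given as a check. Germline genes had 2 tested members, endothelial markers 3 and leukocyte markers 2, so these lists were not tested.

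The rule for naming genes takes the 8 largest changes in each direction among called genes with a mean of at least 5 CPM in a compared group, a regular gene symbol and, outside the interaction, no overlap between the libraries of both groups. It adds up to 4 members with the smallest adjusted p of each list discussed, MDM2, CDKN1A and IDH1 in every comparison, and the 6 p53 targets with the smallest adjusted p in the interaction. The results of some genes that the rule names are not reported here.

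The first alternatives were DESeq2 1.42.0, DESeq2 size factors, library totals, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, a fit of only the 2 groups compared, and leaving out each library in turn. For the lists they were an estimated correlation, library totals, a prior count of 0.5, the block and each library in turn, and for the agreement of the Nutlin responses genes of at least 5 CPM and each library in turn. After the data were examined, 3 more were added: leaving out 3 libraries that stood apart (vehicle_Nutlin replicates 2 and 3 and AG120 replicate 1, which leaves 1 vehicle_Nutlin library, assumed to vary like the other groups), removing each library's trend with transcript length, and limma voom with library quality weights. Transcript lengths came from GENCODE by symbol and covered 86.1% of the tested genes. They served in no other step.

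The tests were tested on simulated data with the depth of these libraries, where 100 genes changed 1.5-fold and 100 changed 2-fold. Each gene had the same spread in all 4 groups, estimated from these libraries, and genes were drawn independently of each other. The edgeR test recovered between 59% and 64% of the 2-fold changes in the comparisons of 2 groups and 28% in the interaction. At 1.5-fold it recovered between 12% and 17%, and 2% in the interaction. It called between 2 and 6 unchanged genes per comparison, against 13 to 29 for DESeq2. In each comparison camera recovered the raised list and called 0 of 33 unchanged lists. Since the simulated genes were independent, this does not show how often camera calls unchanged lists of correlated genes.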

Results

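Gene expression was measured in RBE cholangiocarcinoma cells by poly(A) RNA sequencing, to ask how 2-HG changes the gene programme that p53 directs. The counts hold no measure of 2-HG or of IDH1 activity, so the comparisons are of AG-120 with vehicle. Cells had received vehicle or AG-120 for 22 days, then 72 hours without or with Nutlin, and each of the 4 groups held 3 libraries. MDM2 (hg19 chromosome 12, 69201956 to 69239214) and CDKN1A (chromosome 6, 36644305 to 36655116), both direct p53 targets, were high in every Nutlin library. MDM2 stood at 146 ± 6.96 CPM in vehicle, 2845 ± 694 in vehicle_Nutlin, 163 ± 26.4 in AG120 and 3340 ± 16 CPM in AG120_Nutlin (mean ± SD, n = 3). CDKN1A, which encodes the cell cycle inhibitor p21, stood at 379 ± 13, 8437 ± 837, 446 ± 57.9 and 10218 ± 167 CPM in the same order. IDH1 (chromosome 2, 209100951 to 209130798) was at 171 ± 2.75, 110 ± 19.3, 195 ± 8.97 and 102 ± 1.96 CPM in the same order.

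**Figure D1:**
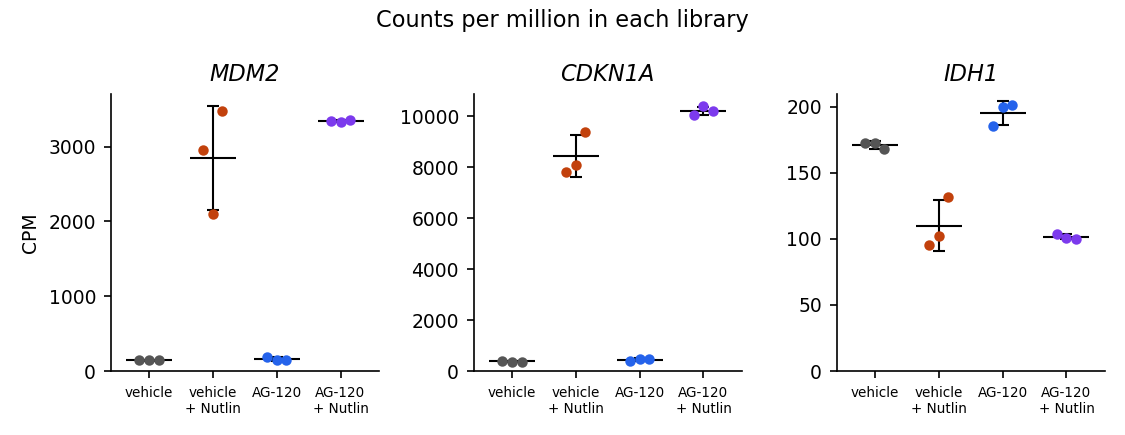
CPM (vertical axis, starting at 0) of MDM2, CDKN1A and IDH1 in each of the 12 libraries, by group. Points are libraries, and bars give the mean and SD of 3. CDKN1A averaged 379 CPM in vehicle and 446 in AG120 against 8437 and 10218 CPM after Nutlin.

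Nutlin set the libraries apart more than anything else: the first principal component held 76.7% of the variance and parted the libraries with and without Nutlin. The next components followed single libraries: 7.88% of the variance with vehicle_Nutlin replicate 3, 4.89% with vehicle_Nutlin replicate 2 and 3.11% with AG120 replicate 1. A fit without these 3 libraries holds 1 vehicle_Nutlin library, whose spread is not measured and was assumed to be like that of the other groups. Replicates were closest in AG120_Nutlin, with a median SD of 0.07 (log2) per gene, and in vehicle, with 0.08. The median SD was 0.14 in AG120 and 0.23 in vehicle_Nutlin. In vehicle_Nutlin replicate 3, 9.67% of genes lay over 2-fold from the mean of the other two libraries of its group. Libraries of these groups also differed by transcript length. The correlation across genes (which are not independent replicates) of a library's deviation from the other two with transcript length was 0.468, 0.267 and -0.426 (Spearman) in vehicle_Nutlin replicates 1, 2 and 3. It was 0.504, -0.356 and -0.484 in AG120 replicates 1, 2 and 3, and between -0.100 and 0.117 in all vehicle and AG120_Nutlin libraries.

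**Figure D2:**
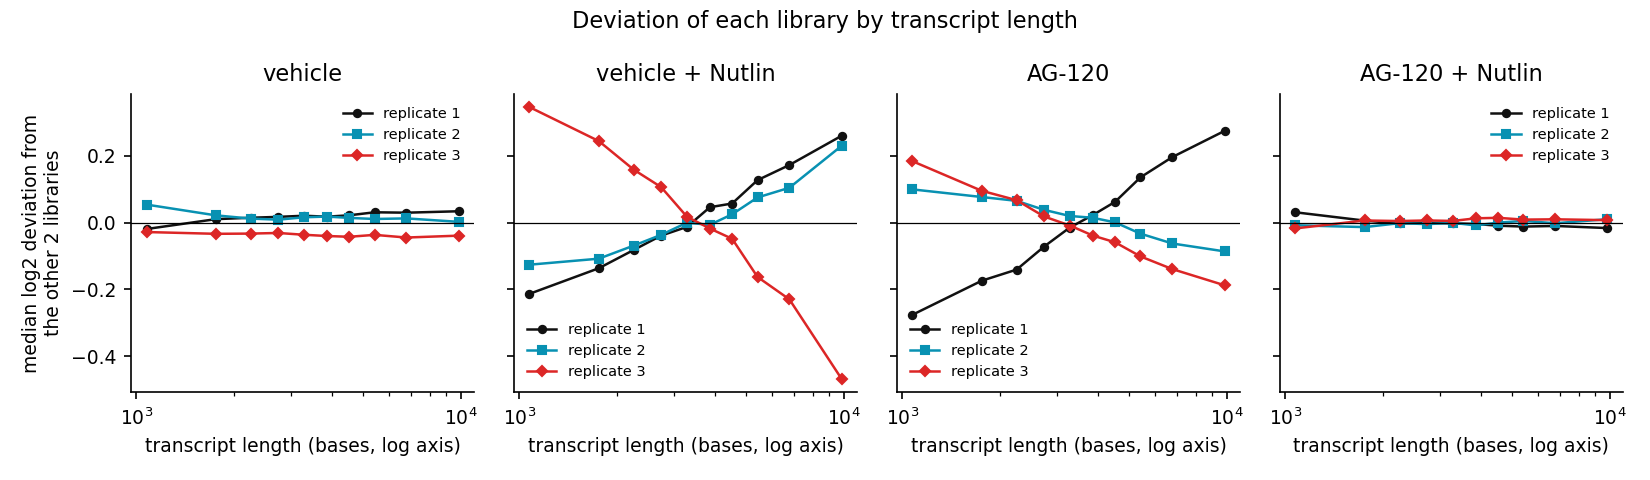
Median log2 deviation of each library from the other 2 libraries of its group (vertical axis) against transcript length in bases (horizontal log axis), 1 panel per group and 1 line per replicate. The lines of vehicle_Nutlin and AG120 tilt, with Spearman correlations across genes from -0.484 to 0.504, while those of vehicle and AG120_Nutlin stay flat.

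The first comparison asked what p53 activation did in cells kept in vehicle. Nutlin raised p53 targets and lowered cell cycle genes in vehicle cells. TP53I3, a pro-apoptotic p53 target, rose 106-fold, from 8.02 ± 1.78 to 855 ± 51.5 CPM (mean ± SD, n = 3). CDKN1A rose 22.2-fold and MDM2, the ubiquitin ligase that restrains p53, rose 19.5-fold. TOP2A, the topoisomerase of dividing cells (chromosome 17, 38544768 to 38574202), fell 51.6-fold, from 741 ± 24.7 to 14.4 ± 1.18 CPM. In all, 4206 genes were higher and 4258 lower, and 1855 and 2181 of these changed at least 2-fold.

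Of 120 measured p53 targets, 108 rose and 2 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 2.08 (camera adjusted p = 2.491e-33). All 6 lists by function were higher. Among arrest targets 11 of 13 rose, among them BTG2 (4.16), SESN1 (3.49) and TRIM22 (4.71), with adjusted p = 8.187e-08 for the list. Among apoptosis targets 20 of 21 rose, among them the death receptor FAS (2.91) and EDA2R (5.03), with adjusted p = 3.983e-13. The metabolic targets counted 16 of 18 higher and 1 lower (adjusted p = 1.178e-10), with GLS2, a glutaminase, at 4.65 and FDXR at 4.14. DNA repair targets counted 6 of 9 higher and 1 lower (adjusted p = 0.003827), with RRM2B at 3.01, XPC at 2.02 and DDB2 at 2.05. Of the other targets 54 of 56 rose (adjusted p = 3.1e-24). Of 12 feedback regulators 8 rose and 1 fell (adjusted p = 0.001287): PPM1D, a phosphatase that acts on p53, rose by 2.43 on the log2 scale, while TP73, a p53 relative that E2F1 is known to activate, fell 46.7-fold to 0.432 ± 0.223 CPM.

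Among called genes with at least 5 CPM in a compared group and no overlap between the groups, the largest rises started from under 0.1 CPM. CLCA2, a known p53 target (chromosome 1, 86889769 to 86922241), had 0 counts in all 3 vehicle libraries and 542 ± 110 CPM after Nutlin, at least 12057-fold higher. LCE1C was at least 1435-fold, HHATL at least 614-fold, UNC45B at least 399-fold and LCE1F at least 380-fold higher, all against 0 counts. LCE1C and LCE1F belong to the late cornified envelope genes of skin. LCE1B rose to 63.2 ± 1.17, DRAXIN to 128 ± 76.1 and LCN15 to 35.9 ± 7.23 CPM, each from under 0.1 CPM. The 8 largest falls under the same limits were KIF18B (-8.19), ASPM (-8.02), KIF14 (-7.96), GTSE1 (-7.92), DLGAP5 (-7.61), E2F2 (-7.56), SPC25 (-7.39) and TICRR (-7.39).

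Of 50 G1/S genes 47 fell (48 adjusted over the list alone) and 2 rose, with a median log2 fold change of -3.20 (adjusted p = 3.121e-22). TK1, a thymidine kinase of S phase, fell 89.1-fold and MCM6 fell 10.9-fold. Of 59 G2/M genes 56 fell and 0 rose (57 and 0 adjusted over the list alone), with a median of -5.30 (adjusted p = 3.226e-30), and ANLN, needed for cytokinesis, fell 89.8-fold. Ribosome biogenesis genes were lower too: 20 of 30 fell and 1 rose (median -0.68, adjusted p = 9.12e-05), with DKC1 at -1.09 and GNL3 at -1.02. Histone mRNAs went the other way, although most histone mRNAs are made in S phase and lack a poly(A) tail: 8 of 10 rose (median 2.37, adjusted p = 4.436e-05), with HIST1H2AC at 3.14 and HIST2H2BE at 3.51. RMRP, RPPH1 and RN7SK, other RNAs without a tail, stood at 77.4, 174 and 163 CPM in vehicle_Nutlin replicate 2. They stood at 1.01, 0.37 and 1.69 CPM in replicate 1 and at 0.47, 0.513 and 1.15 CPM in replicate 3. Whether carry-over of such RNA added to the histone rise was not tested. All calls in this paragraph and all 7 lists of p53 targets kept an adjusted p under 0.05 with an estimated correlation, at most 0.03542.

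Lipid genes were lower after Nutlin. Of 23 cholesterol synthesis genes 18 fell and 2 rose (median -1.71, adjusted p = 5.854e-08; adjusted p = 0.08382 with an estimated correlation): LSS, a sterol cyclase, fell 7.6-fold from 241 ± 13.8 CPM, and HMGCS1 6.81-fold. Of 16 fatty acid synthesis genes 10 fell and 1 rose (adjusted p = 0.0006741; adjusted p = 0.05485 with an estimated correlation), with the desaturase SCD at -2.33 and ELOVL6 at -1.68. Lysosome and autophagy genes were higher, with 23 of 30 up and 1 down (adjusted p = 8.187e-08; adjusted p = 0.05863 with an estimated correlation), among them the protease CTSD (1.89) and the autophagy receptor SQSTM1 (1.68). NRF2 targets, which respond to oxidative stress, counted 17 of 25 higher and 4 lower (adjusted p = 0.0002332; adjusted p = 0.1785 with an estimated correlation). The haem oxygenase HMOX1 rose by 3.74 and AKR1C1 by 5.03 on the log2 scale.

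Of 17 mesenchymal genes 11 fell and 2 rose (adjusted p = 0.02845; adjusted p = 0.1018 with an estimated correlation), with N-cadherin CDH2 at -1.31 and THBS1 at -1.91. Of 21 epithelial junction genes 13 fell and 6 rose (adjusted p = 0.0232; adjusted p = 0.2598 with an estimated correlation), with E-cadherin CDH1 at -1.66 and CLDN3 at -2.25. All 5 tested fibroblast markers fell (adjusted p = 0.006732, and 0.1682 with an estimated correlation), among them COL1A1 (-4.47) and PDGFRB (-2.59), which stood at 21 ± 1.86 and 16.3 ± 0.597 CPM in vehicle. Signs of RNA composition moved with Nutlin as well. Mitochondrially encoded genes counted 8 of 13 higher (median 1.02, adjusted p = 0.009488; adjusted p = 0.5858 with an estimated correlation), and their share of counts was 1.02% to 1.35% in vehicle and 1.71% to 3.45% in vehicle_Nutlin libraries. Ribosomal protein genes counted 14 of 32 higher (median 0.34, adjusted p = 0.006916; adjusted p = 0.6405 with an estimated correlation). No other list was called in this comparison. Without vehicle_Nutlin replicate 2 xenobiotic response genes were called higher (adjusted p = 0.04868). Without vehicle_Nutlin replicate 3 the calls for mesenchymal genes and ribosomal protein genes ended (adjusted p = 0.06726 and 0.1552). When the 3 libraries that stood apart were left out, with 1 vehicle_Nutlin library left, the calls for epithelial junction genes and ribosomal protein genes ended (adjusted p = 0.05334 and 0.357). With voom weights the call for ribosomal protein genes ended (adjusted p = 0.1356). Biliary markers had a median of 0.04, a mean of -0.04 and an adjusted p of 0.9137, which differ in sign.

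The second comparison asked the same in cells kept in AG-120. The response was again one of p53 targets up and cell cycle genes down. TP53I3 rose 118-fold, CDKN1A 22.9-fold from 446 ± 57.9 to 10218 ± 167 CPM, and GDF15, a secreted stress factor, by 5.47 on the log2 scale. TOP2A fell 68.2-fold to 9.94 ± 0.463 CPM (mean ± SD, n = 3) and ANLN fell 144-fold. Here 4234 genes were higher and 4513 lower, 2028 and 2392 of them at least 2-fold.

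Of 120 p53 targets 106 rose and 4 fell (106 and 5 adjusted over the list alone), with a median log2 fold change of 2.18 (adjusted p = 3.86e-30; adjusted p = 0.0003887 with an estimated correlation). FAS was at 2.87, EDA2R at 5.60, PPM1D at 2.65 and GLS2 at 4.66, and TP73 was again lower (-5.39). Of 50 G1/S genes 46 fell and 2 rose (median -3.03, adjusted p = 5.434e-20), and of 59 G2/M genes 57 fell and 0 rose (median -5.46, adjusted p = 1.751e-28). Under the same limits on level and overlap the largest falls were UBE2C (-8.84), SPC25 (-8.65), ASPM (-8.42), ESCO2 (-8.12), NEK2 (-8.04), MYBL2 (-8.01), MCM10 (-7.96) and KIF18B (-7.93). Against 0 counts in AG120, LCE1B was at least 1383-fold, LCE1C at least 1315-fold, HHATL at least 721-fold, LCN15 at least 695-fold, BLNK at least 597-fold, UNC45B at least 406-fold and RGMA at least 329-fold higher. CLCA2 went from 0.0327 ± 0.0566 to 612 ± 20 CPM.

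Cholesterol synthesis genes fell in 19 of 23 cases and rose in 2 (median -2.08, adjusted p = 6.967e-09; adjusted p = 0.06563 with an estimated correlation), with HMGCS1 at -3.18, LSS at -3.11 and DHCR7 at -2.83. Fatty acid synthesis genes fell in 10 of 16 (adjusted p = 0.04913 with an estimated correlation) and ribosome biogenesis genes in 22 of 30 (adjusted p = 0.02795 with an estimated correlation). Histones rose in 8 of 10 and fell in 1 (adjusted p = 0.001325). RMRP, RPPH1 and RN7SK were raised in AG120 replicates 1 and 2 and in AG120_Nutlin replicate 3, and carry-over was not tested here. Type I interferon genes were lower, with 20 of 34 down and 4 up (median -0.77, adjusted p = 0.004846; adjusted p = 0.1463 with an estimated correlation), led by OAS3 (-4.92). Antigen presentation genes counted 10 of 22 lower and 2 higher (adjusted p = 0.03585; adjusted p = 0.2539 with an estimated correlation), with CD74 at -2.36, while TAP1, also a p53 target, rose by 2.22. YAP and TGF-beta targets counted 14 of 23 lower and 6 higher (adjusted p = 0.03585; adjusted p = 0.3517 with an estimated correlation). The matricellular genes THBS1 (-3.24) and CYR61 (-3.20) fell, while BHLHE40 rose by 2.66. Fibroblast markers (5 of 5 lower), mesenchymal genes (11 of 17 lower, 4 higher), epithelial junction genes (12 of 21 lower, 4 higher), NRF2 targets (18 of 25 higher, 3 lower), lysosome and autophagy genes (22 of 30 higher, 2 lower) and mitochondrially encoded genes (11 of 13 higher) were called too. With an estimated correlation their adjusted p was 0.1429, 0.06563, 0.1874, 0.1429, 0.06656 and 0.3517. Xenobiotic response genes were not called (adjusted p = 0.0565), but were called higher without AG120 replicate 1 or 3 or AG120_Nutlin replicate 1 (adjusted p = 0.04822, 0.0411 and 0.03654) and with library totals (adjusted p = 0.04525). Ribosomal protein genes were not called (adjusted p = 0.1617), but were called lower with voom weights on all libraries (adjusted p = 0.00785) and without the 3 libraries that stood apart (adjusted p = 0.00402).

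Across the 15691 genes the Nutlin responses with and without AG-120 lay on 1 line, with a Spearman correlation of 0.875 and a Pearson correlation of 0.920. The least-squares slope was 0.96 (AG-120 on vehicle cells), and noise in the vehicle response lowers it. An orthogonal slope, which treats both responses alike, was 1.05. Genes are not independent replicates, so no p is given. Both responses shared 3451 higher genes, where independent lists of these sizes would share 1135, and 3587 lower genes, where they would share 1225. Only 13 genes were called in opposite directions. For the 120 p53 targets the Pearson correlation was 0.964, the least-squares slope 1.01 and the orthogonal slope 1.05.

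**Figure D3:**
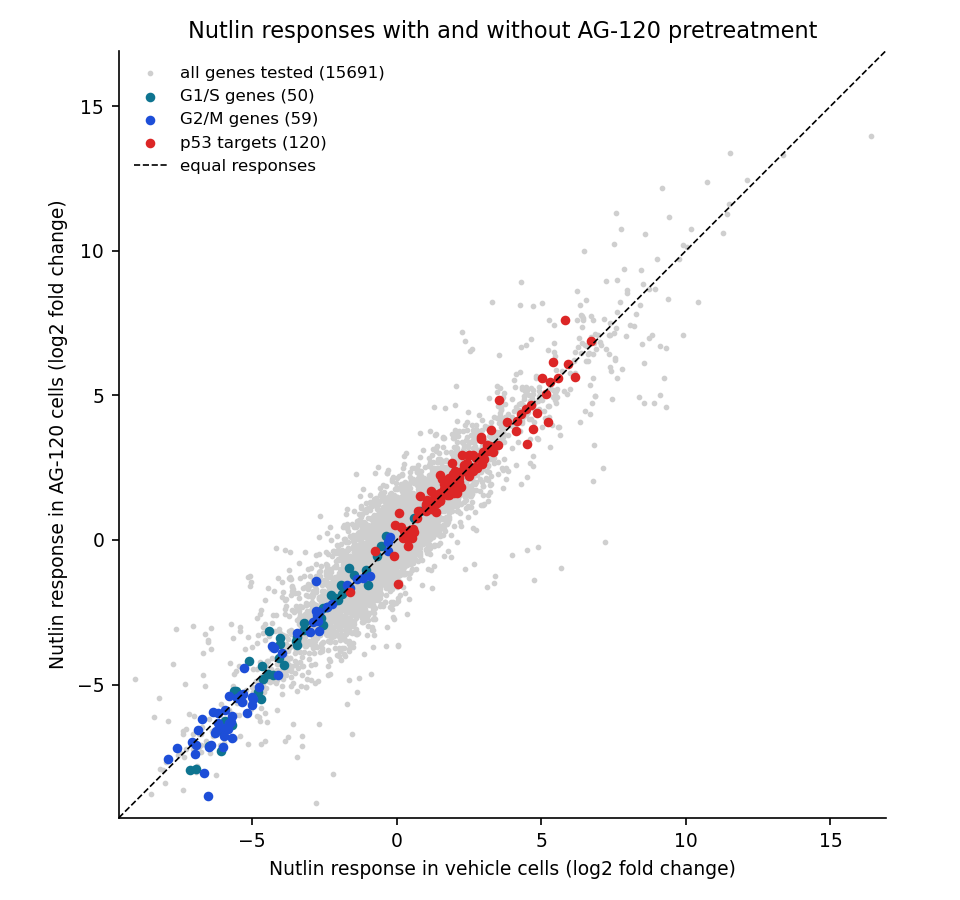
Log2 fold change with Nutlin in vehicle cells (horizontal) against AG-120 cells (vertical) for the 15691 genes tested, with p53 targets (120), G1/S genes (50) and G2/M genes (59) in colour and the line of equal responses. Fitted values above about 11 belong to genes with few or no counts before Nutlin and are no measure of size. The coloured genes follow the line, with a Pearson correlation of 0.964 for p53 targets.

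The third comparison asked what 22 days of AG-120 did by itself. Few single genes were called, by a test that recovered 12% of 1.5-fold changes in simulated data for this comparison. MUC5AC, a gel-forming mucin of gastric and biliary epithelium (chromosome 11, 1151580 to 1222364), rose 14-fold, from 0.603 ± 0.164 to 8.34 ± 2.16 CPM (mean ± SD, n = 3), and was higher in 3 of 3 AG120 libraries. BAAT, which conjugates bile acids, rose 3.1-fold, from 4.93 ± 0.531 to 15.2 ± 1.13 CPM, and NPC1L1, a cholesterol transporter, rose 2.92-fold to 13.4 ± 2.04 CPM. The other called genes were ABCA12 (1.11), KCNJ16 (1.04), HABP2 (0.92), TRIM22 (0.87) and the complement gene C3 (0.83), so that 8 genes were higher and 0 lower with edgeR. MDM2 (0.16), CDKN1A (0.23) and IDH1 (0.19) did not pass.

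Several lists were called as a whole while few of their members passed alone. Another grouping of the same libraries called 13 lists, against 18 for the real one, so chance was not excluded for these list calls. Of 34 type I interferon genes 31 had a positive change (median 0.24), and the list was higher with adjusted p = 5.785e-10 (adjusted p = 0.01811 with an estimated correlation), but TRIM22 alone passed with all 12 libraries, and 5 genes without the 3 libraries that stood apart. Cholesterol synthesis genes had 22 of 23 members positive (median 0.22, adjusted p = 1.384e-08; adjusted p = 0.09687 with an estimated correlation), with 0 called by edgeR over all genes, 7 adjusted over the list alone and 13 without the 3 libraries that stood apart. Fatty acid synthesis genes had 14 of 16 positive (adjusted p = 5.579e-05; adjusted p = 0.04383 with an estimated correlation), with SCD at 0.54 and ELOVL6 at 0.55. Biliary markers were higher (adjusted p = 0.00116; adjusted p = 0.03356 with an estimated correlation), with KRT19 at 0.37 beside MUC5AC. Hepatocyte markers had 11 of 15 positive (adjusted p = 0.02783; adjusted p = 0.09687 with an estimated correlation), with HNF4A, a hepatocyte transcription factor, at 0.60. Antigen presentation genes had 19 of 22 and epithelial junction genes 16 of 21 positive (adjusted p = 0.0001801 and 0.0003171; adjusted p = 0.09687 with an estimated correlation for each).

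Proliferation genes were lower. Of 50 G1/S genes 49 had a negative change (median -0.21, adjusted p = 6.174e-09; adjusted p = 0.004287 with an estimated correlation), and G2/M genes had a median of -0.16 (adjusted p = 1.105e-05; adjusted p = 0.0144 with an estimated correlation), with 0 members of either called by edgeR with all 12 libraries, and 18 and 17 lower without the 3 libraries that stood apart. CDC6 was at -0.38 and CDC20 at -0.33. Ribosome biogenesis genes (median -0.07, adjusted p = 0.005096; adjusted p = 0.09687 with an estimated correlation) and MAPK output genes (median -0.16, adjusted p = 0.02961; adjusted p = 0.2759 with an estimated correlation) were lower too. The p53 targets had a median of 0.05 (adjusted p = 0.004166, and 0.1444 with an estimated correlation), with 2 higher over all genes and 7 adjusted over the list alone. Without the 3 libraries that stood apart their median was 0.11. Metabolic p53 targets were called as well (median 0.16, adjusted p = 0.0003332; adjusted p = 0.09687 with an estimated correlation), with 17 of 18 positive. Histones had 10 of 10 positive (median 0.83, adjusted p = 2.493e-10; adjusted p = 0.004287 with an estimated correlation). RMRP, RPPH1 and RN7SK, RNAs without a poly(A) tail chosen after their values were seen, were raised in AG120 replicates 1 and 2 beside them. Xenobiotic response genes, YAP and TGF-beta targets, mitochondrially encoded genes and housekeeping genes were also called, up, up, up and down (adjusted p = 0.02545, 0.02961, 0.01743 and 0.01749), with adjusted p = 0.1439, 0.3718, 0.4985 and 0.4985 with an estimated correlation.

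Single libraries changed list calls for AG-120 without Nutlin. Without AG120 replicate 1 the calls for MAPK output genes, mitochondrially encoded genes and housekeeping genes ended (adjusted p = 0.06663, 0.1147 and 0.1505), and p53 arrest targets, p53 apoptosis targets, p53 other targets, secretory inflammatory genes, ATF4 targets and lysosome and autophagy genes were called higher (adjusted p = 0.0001275, 0.008609, 0.0005166, 0.004983, 0.008675 and 0.004983). Without AG120 replicate 2 the calls for all p53 targets and YAP and TGF-beta targets ended (adjusted p = 0.061 and 0.09878), and unfolded protein genes were called lower (adjusted p = 0.04433). Without AG120 replicate 3 the calls for all p53 targets, hepatocyte markers, xenobiotic response genes, MAPK output genes, YAP and TGF-beta targets and ribosome biogenesis genes ended (adjusted p = 0.0735, 0.09074, 0.0735, 0.09074, 0.09074 and 0.09074). Without vehicle replicate 1 the calls for MAPK output genes and mitochondrially encoded genes ended (adjusted p = 0.1423 and 0.07396). Without vehicle replicate 2 the calls for xenobiotic response genes, MAPK output genes, mitochondrially encoded genes and housekeeping genes ended (adjusted p = 0.05091, 0.0554, 0.08599 and 0.05091), and NRF2 targets and lysosome and autophagy genes were called higher (adjusted p = 0.02586 and 0.02586). Without vehicle replicate 3 the calls for hepatocyte markers and YAP and TGF-beta targets ended (adjusted p = 0.1284 and 0.09882). When the 3 libraries that stood apart were left out, the call for housekeeping genes ended (adjusted p = 0.2044), and p53 arrest targets, p53 apoptosis targets, p53 other targets, secretory inflammatory genes, ATF4 targets, NRF2 targets and lysosome and autophagy genes were called higher (adjusted p = 0.0008854, 0.002943, 0.002943, 0.003924, 0.005614, 0.04231 and 0.0007267). With the length trend removed the call for housekeeping genes ended (adjusted p = 0.06656), and ATF4 targets, NRF2 targets and lysosome and autophagy genes were called higher (adjusted p = 0.03133, 0.03187 and 0.01605). With voom weights the call for housekeeping genes ended (adjusted p = 0.05302), and p53 arrest targets, p53 apoptosis targets, p53 other targets, secretory inflammatory genes, ATF4 targets, NRF2 targets and lysosome and autophagy genes were called higher (adjusted p = 0.004875, 0.002177, 0.002068, 0.04113, 0.003093, 0.02169 and 0.001623). In the other settings run, apart from the estimated correlation, the calls named here as ended held.

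Counts of single genes were small in this comparison and moved with the libraries and the tool: 1254 genes had an unadjusted p under 0.05, where 784.55 would by chance, and DESeq2 called 85 higher and 23 lower. The 8 of AG-120 effect without Nutlin: genes higher, became 4, 2 or 1 without vehicle replicate 1, 2 or 3, and 608 without the 3 libraries that stood apart. The 0 of AG-120 effect without Nutlin: genes lower, became 1 without AG120 replicate 1 or 3, and 300 without those 3 libraries.

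The fourth comparison asked what AG-120 changed in Nutlin-treated cells. CTGF, a secreted YAP and TGF-beta target (chromosome 6, 132269316 to 132272513), was 3.05-fold lower, at 94.9 ± 6.84 CPM in vehicle_Nutlin and 31.1 ± 1.35 CPM in AG120_Nutlin (mean ± SD, n = 3). The aldehyde oxidase AOX1 was 3.31-fold lower, at 12.5 ± 2.43 and 3.8 ± 0.277 CPM, and the proto-oncogene MYC was lower by a log2 fold change of -1.25. In all 303 genes were lower and 68 higher, 71 and 10 of them at least 2-fold. These calls pool the spread over all 4 groups, although the median SD (log2) per gene was 0.23 in vehicle_Nutlin and 0.07 in AG120_Nutlin. An edgeR fit of only the groups compared, with fewer libraries to measure the spread, called 15 lower and 0 higher.

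Further falls under the naming rule were SGK1 (-1.60), CALB2 (-1.53), RGS4 (-1.52), MEIS3 (-1.51), OXTR (-1.41) and CPA4 (-1.37). Among called genes with at least 5 CPM in a compared group and no overlap between the groups, the largest rises were DOCK8 (1.39), GAS2L3 (1.21), MTRNR2L2 (1.11), NLRP1 (1.10), B3GNT9 (1.04), SSTR5 (0.95), PLEKHM3 (0.90) and FAM21B (0.89). MTRNR2L2 is a near copy of mitochondrial ribosomal RNA, and FAM21B has close paralogs. Of 23 YAP and TGF-beta targets 8 fell and 0 rose (9 and 4 adjusted over the list alone): beside CTGF, ANKRD1 was at -1.33, CYR61 at -1.19 and TGFB2 at -1.07 (list adjusted p = 0.02588; adjusted p = 0.433 with an estimated correlation). Of 59 G2/M genes 9 fell and 1, GAS2L3, rose (median -0.29, adjusted p = 0.0001641; adjusted p = 0.08637 with an estimated correlation), with BUB1B at -0.85 and AURKA at -0.77. Of 50 G1/S genes 4 fell (adjusted p = 0.01828; adjusted p = 0.2223 with an estimated correlation), among them E2F1 (-1.11) and TK1 (-0.88). The IDH and 2-HG metabolism list had 2 members lower, the transaminase BCAT1 (-1.22) and PHGDH of serine synthesis (-0.86), with adjusted p = 0.00167 (adjusted p = 0.2369 with an estimated correlation).

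NRF2 targets were higher, 7 of 25 and 0 lower (median 0.27, adjusted p = 0.0003205; adjusted p = 0.2495 with an estimated correlation): AKR1B10, an aldo-keto reductase, rose 1.8-fold, from 228 ± 45.1 to 410 ± 15.2 CPM, and HMOX1 1.61-fold. Xenobiotic response genes counted 2 of 13 higher (adjusted p = 0.02938; adjusted p = 0.2369 with an estimated correlation), NQO1 (0.51) and ABCC2 (0.41), both also NRF2 targets. Ribosomal protein genes counted 16 of 32 lower (29 adjusted over the list alone; median -0.58, adjusted p = 8.915e-18; adjusted p = 0.2495 with an estimated correlation), with RPL32 at -0.80 and RPS2 at -0.69. Ribosome biogenesis genes counted 4 of 30 lower (adjusted p = 0.0001249; adjusted p = 0.1202 with an estimated correlation), among them NPM1 (-0.46), and fibroblast markers 2 of 5 lower (adjusted p = 0.0439; adjusted p = 0.3814 with an estimated correlation). The share of mitochondrial counts was 1.71% in vehicle_Nutlin replicate 3, up to 3.45% in the other two libraries of that group, and 4.11% to 4.42% in AG120_Nutlin. That list had 13 of 13 members positive and 0 called (adjusted p = 9.92e-05; adjusted p = 0.4184 with an estimated correlation), and housekeeping genes had 1 lower (adjusted p = 0.001659; adjusted p = 0.5042 with an estimated correlation).

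Among the 120 p53 targets 1 rose, ABCA12 (0.64), and 3 fell, TNFRSF10C (-1.62) and PLK2 (-0.56) among them (3 higher and 3 lower adjusted over the list alone). Without the 3 libraries that stood apart 25 were higher and 3 lower. Their median was 0.13 (adjusted p = 0.004245; adjusted p = 0.2369 with an estimated correlation). The DNA repair and the other targets were called with medians of 0.21 and 0.15 (adjusted p = 0.02764 and 0.004245; adjusted p = 0.2223 with an estimated correlation for each). MDM2 (0.23), CDKN1A (0.28) and IDH1 (-0.11) did not pass. The 68 of AG-120 effect with Nutlin: genes higher, became 418 without vehicle_Nutlin replicate 1, 203 without vehicle_Nutlin replicate 3 and 7, 5 or 6 without AG120_Nutlin replicate 1, 2 or 3. The 303 of AG-120 effect with Nutlin: genes lower, became 619, 480 and 73, 56 or 72 without the same libraries. Without the 3 libraries that stood apart, with 1 vehicle_Nutlin library left, the counts were 629 and 745.

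List calls for AG-120 with Nutlin changed with the libraries too. Without AG120_Nutlin replicate 1 the call for fibroblast markers ended (adjusted p = 0.05913). Without AG120_Nutlin replicate 2 mesenchymal genes were called lower (adjusted p = 0.03323). Without AG120_Nutlin replicate 3 the calls for xenobiotic response genes and fibroblast markers ended (adjusted p = 0.05637 and 0.06226). Without vehicle_Nutlin replicate 1 the calls for all p53 targets, p53 DNA repair targets, p53 other targets, G1/S genes, NRF2 targets, xenobiotic response genes, YAP and TGF-beta targets and fibroblast markers ended (adjusted p = 0.1083, 0.05793, 0.1083, 0.08248, 0.05793, 0.1083, 0.2331 and 0.7475). Without vehicle_Nutlin replicate 2 the calls for xenobiotic response genes and YAP and TGF-beta targets ended (adjusted p = 0.133 and 0.06826). Without vehicle_Nutlin replicate 3 p53 apoptosis targets, p53 metabolic targets and lysosome and autophagy genes were called higher (adjusted p = 0.01126, 0.01515 and 0.003044), and mesenchymal genes were called lower (adjusted p = 0.0007661). When the 3 libraries that stood apart were left out, the calls for IDH and 2-HG metabolism genes and housekeeping genes ended (adjusted p = 0.1359 and 0.07425), p53 arrest targets, p53 apoptosis targets, p53 metabolic targets and lysosome and autophagy genes were called higher (adjusted p = 0.04873, 0.007507, 0.001392 and 0.0007997), and mesenchymal genes were called lower (adjusted p = 0.0011). With the length trend removed the calls for p53 DNA repair targets and housekeeping genes ended (adjusted p = 0.0582 and 0.05084), replication-dependent histones and lysosome and autophagy genes were called higher (adjusted p = 0.0359 and 0.0359), and mesenchymal genes were called lower (adjusted p = 0.02963). With a prior count of 0.5 the call for fibroblast markers ended (adjusted p = 0.07296). With voom weights the call for G1/S genes ended (adjusted p = 0.05803), p53 arrest targets, p53 apoptosis targets, p53 metabolic targets and lysosome and autophagy genes were called higher (adjusted p = 0.03798, 0.000607, 0.0009147 and 0.001099), and mesenchymal genes were called lower (adjusted p = 0.0002365). Without those 3 libraries, which leaves 1 vehicle_Nutlin library, member counts differed as well: 12 YAP and TGF-beta targets were lower and 5 higher, 9 G1/S genes lower and 2 higher, 13 NRF2 targets and 5 xenobiotic response genes higher, and 25 ribosomal protein genes and 9 ribosome biogenesis genes lower. In the same fit 8 mitochondrially encoded genes were higher, and 4 IDH and 2-HG metabolism genes, 4 fibroblast markers and 3 housekeeping genes lower. In the other settings run, apart from the estimated correlation, the calls named here as ended held.

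The last comparison tested the difference between the Nutlin responses, the question of the series. No difference was found for the p53 programme as a whole: the mean log2 response of the 120 p53 targets in AG-120 cells exceeded that in vehicle cells by 0.06 (95% interval -0.05 to 0.17), and by 0.01 (-0.04 to 0.07) without the 3 libraries that stood apart, where 1 vehicle_Nutlin library was left and the interval takes its spread from the other groups. What differed was a set of 57 genes, 52 of them with a lower response in AG-120 cells and 5 with a higher one. CTGF stood at 81 ± 10.9 CPM in vehicle and 94.9 ± 6.84 in vehicle_Nutlin, but at 95.3 ± 15.4 in AG120 and 31.1 ± 1.35 CPM in AG120_Nutlin (mean ± SD, n = 3), a log2 difference of -1.85 (adjusted p = 0.001464). BCAT1, which makes glutamate from branched-chain amino acids (chromosome 12, 24964295 to 25102393), went from 44.2 ± 1.53 to 15.1 ± 1.03 CPM in vehicle cells and from 60.9 ± 10.6 to 6.51 ± 0.731 CPM in AG-120 cells, a difference of -1.68 (adjusted p = 0.001798).

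Of the 52 genes with a lower response, 41 fell with Nutlin in both settings, and 49 fell with Nutlin in AG-120 cells. There were 44 that AG-120 lowered in Nutlin-treated cells, and 4 that it raised without Nutlin. Among genes with at least 5 CPM in a group, the largest differences were MUC5AC (-3.67), BAAT (-2.18), SLC16A12 (-2.11), ANKRD2 (-2.05), AOX1 (-1.90), CTGF, BCAT1 and the metalloproteinase MMP24 (-1.61). MUC5AC returned from 8.34 ± 2.16 CPM in AG120 to 0.657 ± 0.221 CPM in AG120_Nutlin, near its level in vehicle. YAP and TGF-beta targets held 7 of the 52 genes, among them ANKRD1 (-1.61), the growth factor TGFB2 (-1.36), THBS1 (-1.33) and CYR61 (-1.10), and 0 with a higher response (9 lower and 1 higher adjusted over the list alone). As a list they were lower with adjusted p = 0.001267 (adjusted p = 0.2958 with an estimated correlation). Serine and proline synthesis genes among ATF4 targets, PHGDH (-1.08) and PYCR1 (-0.99), had lower responses (list adjusted p = 0.03313; adjusted p = 0.2958 with an estimated correlation). So had the keratin KRT7 (-1.18), the claudin CLDN1 (-1.07), PDGFRB (-1.23) and DHCR7, the last enzyme of cholesterol synthesis (-0.81).

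The 5 genes with a higher response were LAMA4 (1.98), GAS2L3 (1.36), HMOX1 (0.96), IGFBP4 (0.92) and SLC6A6 (0.87). HMOX1 (chromosome 22, 35776354 to 35790207) went from 9.71 ± 1.2 to 129 ± 3.01 CPM in vehicle cells and from 8.02 ± 1.54 to 208 ± 3.11 CPM in AG-120 cells. GAS2L3 fell from 41.3 ± 2.63 to 6.03 ± 1.19 CPM and from 37.3 ± 3.92 to 14 ± 1.34 CPM.

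**Figure D4:**
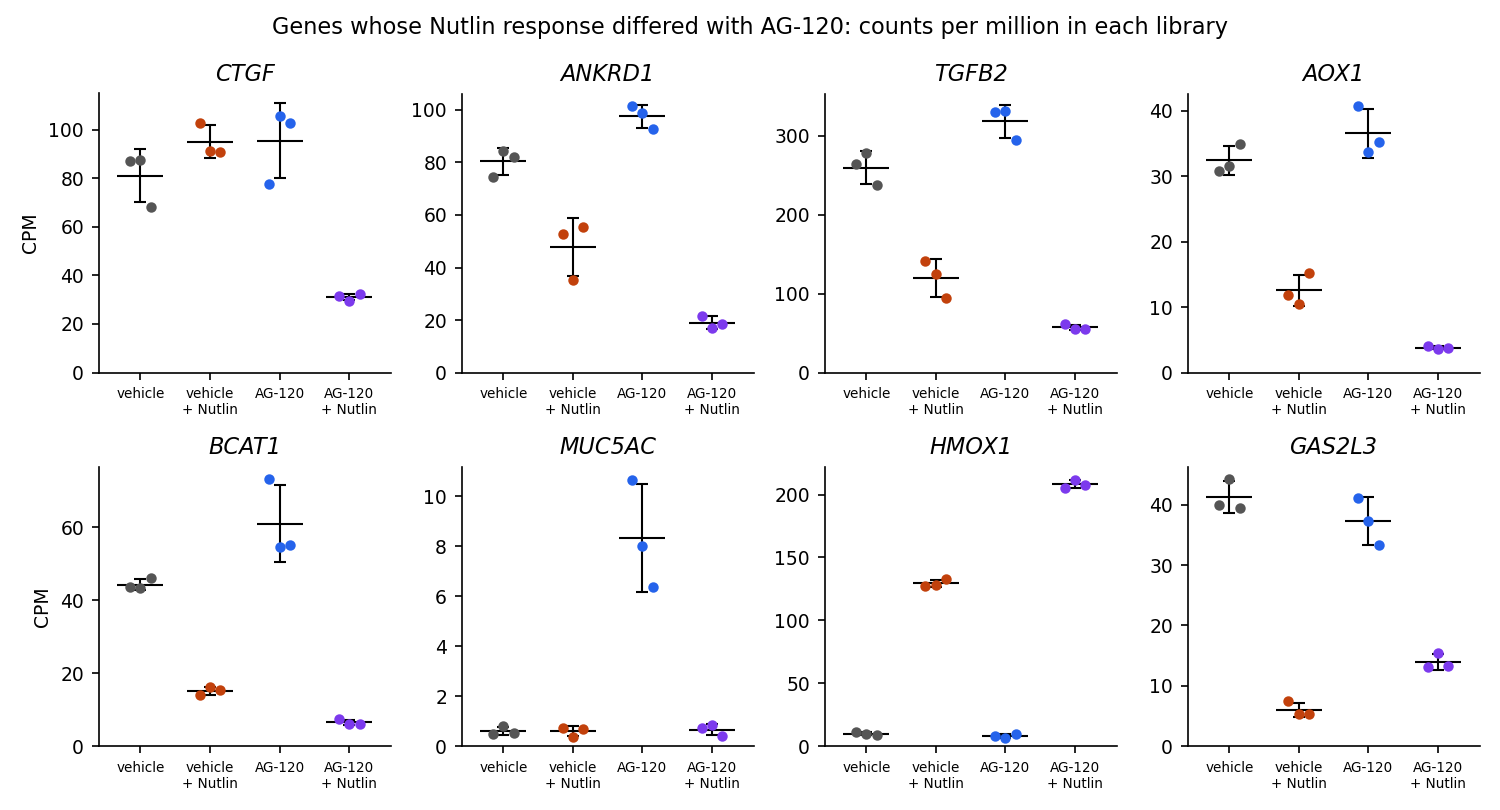
CPM (vertical axes, starting at 0) of 8 genes with a different Nutlin response in AG-120 cells, in each library by group. Points are libraries, and bars give the mean and SD of 3. After Nutlin CTGF averaged 94.9 CPM in vehicle cells and 31.1 CPM in AG-120 cells.

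Of the 120 p53 targets TRIM22 alone was called with all 12 libraries, with a difference of -0.89 (adjusted p = 0.0446): its level after Nutlin was 83.4 ± 10.7 CPM in vehicle and 81.9 ± 2.8 CPM in AG-120 cells, and its level before was 3.16 ± 0.149 and 5.79 ± 0.602 CPM. Without the 3 libraries that stood apart, with 1 vehicle_Nutlin library left, 8 p53 targets were higher and 6 lower. Among the next by adjusted p, these did not pass: GRHL3 (1.32, 0.1191), TNFRSF10C (-1.56, 0.1892) and PLK2 (-0.46, 0.2487). MDM2 (0.07, 0.9291), CDKN1A (0.04, 0.9382) and IDH1 (-0.30, 0.5024) did not pass either. None of the 6 p53 lists by function was called, with adjusted p from 0.2227 for metabolic to 0.7482 for feedback and arrest targets. The median and mean of the members' model changes, not of log2 CPM, differed in sign for arrest (0.04 and -0.01) and apoptosis targets (0.08 and -0.01). G1/S (0.3521) and G2/M genes (0.2517) were not called.

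**Figure D5:**
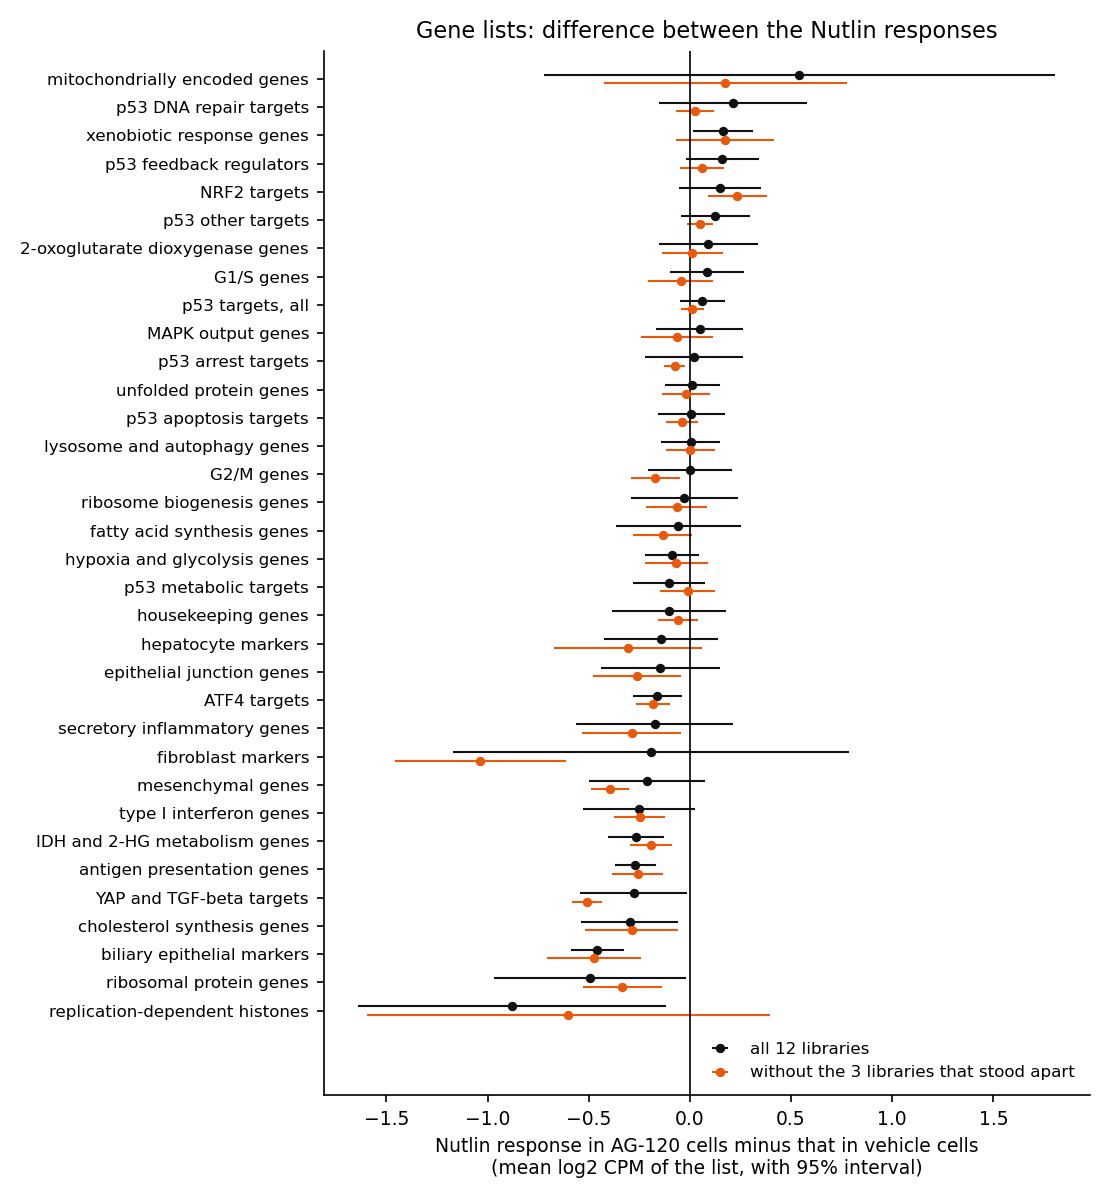
Difference between the Nutlin responses (AG-120 minus vehicle cells) in the mean log2 CPM of each of the 34 gene lists, with 95% intervals, in all 12 libraries and without the 3 libraries that stood apart (1 vehicle_Nutlin library left). The interval of all p53 targets runs from -0.05 to 0.17, and that of biliary markers from -0.59 to -0.32.

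In this comparison 13 of 34 lists were called and 0 kept the call with an estimated correlation. Biliary markers (median -0.34, adjusted p = 0.001267), type I interferon genes (-0.32, 3.502e-05), antigen presentation genes (-0.32, 0.00205), cholesterol synthesis genes (-0.28, 3.502e-05), mesenchymal genes (-0.39, 0.00698) and IDH and 2-HG metabolism genes (-0.17, 0.002153) had lower responses, with adjusted p = 0.07115, 0.1264, 0.2837, 0.2958, 0.1264 and 0.2887 with an estimated correlation. So had histones (-0.79, 4.712e-05), ribosomal protein genes (-0.55, 2.445e-13), epithelial junction genes (-0.23, 0.04886) and fatty acid synthesis genes (-0.13, 0.04132), with adjusted p = 0.07115, 0.3303, 0.4066 and 0.2958 with an estimated correlation. RMRP, RPPH1 and RN7SK were raised in AG120 replicates 1 and 2, in vehicle_Nutlin replicate 2 and in AG120_Nutlin replicate 3 (15.2, 43 and 27.7 CPM). Carry-over of RNA without a tail was therefore not separated from the histone difference. Mitochondrially encoded genes had a higher response (0.36, 0.03025), with adjusted p = 0.584 with an estimated correlation. NRF2 targets in difference between the Nutlin responses were not called (median 0.18, adjusted p = 0.0575), but were called without the 3 libraries that stood apart (adjusted p = 0.0005972), with 7 of 25 higher and 0 lower, in a fit with 1 vehicle_Nutlin library, replicate 1. Their adjusted p ranged from 7.559e-05 with voom weights to 0.5575 with an estimated correlation over the alternatives, and was 0.5247 without vehicle_Nutlin replicate 1.

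Of the 13 list calls 6 changed with the libraries. Without AG120 replicate 1 the call for fatty acid synthesis genes ended (adjusted p = 0.1418), and secretory inflammatory genes were called lower (adjusted p = 0.006161). Without AG120 replicate 2 the calls for epithelial junction genes, ATF4 targets and mitochondrially encoded genes ended (adjusted p = 0.08146, 0.07138 and 0.08928). Without AG120 replicate 3 the calls for epithelial junction genes, ATF4 targets and mitochondrially encoded genes ended (adjusted p = 0.06705, 0.05403 and 0.06705), and ribosome biogenesis genes were called lower (adjusted p = 0.04948). Without AG120_Nutlin replicate 1 the calls for epithelial junction genes, fatty acid synthesis genes, ATF4 targets and mitochondrially encoded genes ended (adjusted p = 0.1516, 0.0736, 0.06624 and 0.06726). Without vehicle replicate 2 the calls for epithelial junction genes and fatty acid synthesis genes ended (adjusted p = 0.06281 and 0.05775). Without vehicle replicate 3 the calls for epithelial junction genes, fatty acid synthesis genes and mitochondrially encoded genes ended (adjusted p = 0.08088, 0.06775 and 0.1093), NRF2 targets were called higher (adjusted p = 0.03013), and ribosome biogenesis genes were called lower (adjusted p = 0.04639). Without vehicle_Nutlin replicate 1 the calls for mesenchymal genes, epithelial junction genes and fatty acid synthesis genes ended (adjusted p = 0.131, 0.2021 and 0.1254). Without vehicle_Nutlin replicate 2 the calls for mesenchymal genes, epithelial junction genes and fatty acid synthesis genes ended (adjusted p = 0.09403, 0.2384 and 0.1007), and fibroblast markers were called lower (adjusted p = 0.03892). Without vehicle_Nutlin replicate 3 the calls for ATF4 targets and mitochondrially encoded genes ended (adjusted p = 0.09037 and 0.6369), NRF2 targets were called higher (adjusted p = 0.001276), and secretory inflammatory genes and ribosome biogenesis genes were called lower (adjusted p = 0.0487 and 0.002833). When the 3 libraries that stood apart were left out, the calls for fatty acid synthesis genes, IDH and 2-HG metabolism genes and mitochondrially encoded genes ended (adjusted p = 0.0527, 0.09147 and 0.1198), NRF2 targets were called higher (adjusted p = 0.0005972), and secretory inflammatory genes and fibroblast markers were called lower (adjusted p = 0.001567 and 5.081e-05). With the length trend removed the call for epithelial junction genes ended (adjusted p = 0.05919), and NRF2 targets were called higher (adjusted p = 0.04176). With library totals the call for epithelial junction genes ended (adjusted p = 0.05584), and NRF2 targets were called higher (adjusted p = 0.04867). With the replicate block the calls for epithelial junction genes and fatty acid synthesis genes ended (adjusted p = 0.0541 and 0.0541). With voom weights NRF2 targets were called higher (adjusted p = 7.559e-05), and secretory inflammatory genes and ribosome biogenesis genes were called lower (adjusted p = 0.005793 and 0.007502). Without those 3 libraries, which leaves 1 vehicle_Nutlin library, 13 YAP and TGF-beta targets were lower and 3 higher. In the other settings run, apart from the estimated correlation, the calls named here as ended held.

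Single libraries moved the counts as well. The 52 of difference between the Nutlin responses: genes lower, became 207 without vehicle_Nutlin replicate 3, 27, 25 or 22 without vehicle replicate 1, 2 or 3, 33 or 30 without AG120 replicate 2 or 3, and 25, 25 or 28 without AG120_Nutlin replicate 1, 2 or 3. The 5 of difference between the Nutlin responses: genes higher, became 34, 3 or 36 without vehicle_Nutlin replicate 1, 2 or 3. They became 1 without any single vehicle or AG120_Nutlin library or AG120 replicate 2, and 3 without AG120 replicate 3. Without the 3 libraries that stood apart, with 1 vehicle_Nutlin library left, 452 genes were lower, all 52 genes among them, and 185 higher.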

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

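The tests in this part other than the splits of the samples were chosen after the result was seen. What called for a closer look was a difference between both Nutlin responses, tested as an interaction term: 52 genes had a lower and 5 a higher response in AG-120 cells. The genes named by the rule were MUC5AC (-3.67), BAAT (-2.18), SLC16A12 (-2.11), ANKRD2 (-2.05), AOX1 (-1.90), CTGF (-1.85), BCAT1 (-1.68), MMP24 (-1.61), ANKRD1 (-1.61), TGFB2 (-1.36), THBS1 (-1.33), PDGFRB (-1.23), KRT7 (-1.18), CYR61 (-1.10), PHGDH (-1.08), CLDN1 (-1.07), PYCR1 (-0.99), TRIM22 (-0.89) and DHCR7 (-0.81), and SLC6A6 (0.87), IGFBP4 (0.92), HMOX1 (0.96), GAS2L3 (1.36) and LAMA4 (1.98). Lists differed too, by their median: replication-dependent histones (-0.79), ribosomal protein genes (-0.55), mesenchymal genes (-0.39), biliary epithelial markers (-0.34), type I interferon genes (-0.32), antigen presentation genes (-0.32), cholesterol synthesis genes (-0.28), epithelial junction genes (-0.23), YAP and TGF-beta targets (-0.18), IDH and 2-HG metabolism genes (-0.17), fatty acid synthesis genes (-0.13), ATF4 targets (-0.13) and mitochondrially encoded genes (0.36). With an estimated correlation 0 of these 13 list calls were kept. Those of ATF4 targets and of mesenchymal, epithelial junction, fatty acid synthesis and mitochondrially encoded genes each ended also in at least 1 fit without a single library, at adjusted p up to 0.09037, 0.131, 0.2384, 0.1418 and 0.6369. Those of fatty acid synthesis, IDH and 2-HG metabolism and mitochondrially encoded genes ended without the 3 libraries that stood apart (0.0527, 0.09147 and 0.1198), with 1 vehicle_Nutlin library left.

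Other splits of the libraries were counted. For the difference, 100 splits were counted, the real one and others drawn at random. Of these, 2 gave as many genes as the real 57, itself included. The other such split called 198 genes, which points to a structure of the samples: it kept the AG-120 labels without Nutlin and swapped all of them with Nutlin, so it measured the sum of the AG-120 effects. Splits that mix AG-120 with vehicle libraries put any AG-120 effect into the spread within groups, which lowers their counts. The share of 2 in 100 therefore does not exclude chance as the source of the gene count. For the lists, 11 of 100 splits called as many as the real 13, the highest other 18, so chance was not excluded for the list calls. The comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. There the real split and the highest other called 8464 and 0 genes for Nutlin in vehicle cells, 8747 and 0 for Nutlin in AG-120 cells, 8 and 0 for AG-120 without Nutlin, and 371 and 0 for AG-120 with Nutlin, each with 1 split as large. For lists they called 20 and 16, 22 and 23 (2 splits as large), 18 and 13, and 14 and 11 (1 split as large in the other comparisons). These splits therefore do not exclude chance for the list calls of these comparisons.

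The first pattern is the 52 genes with a lower Nutlin response in AG-120 cells. Removing each library's trend with transcript length did not remove it: 50 of the 52 genes have an annotated length, and 49 of these 50 stayed called lower. Low weights for the 3 libraries that stood apart did not remove it either. Voom gave vehicle_Nutlin replicates 2 and 3 and AG120 replicate 1 the lowest weights of the 12 libraries (0.473, 0.0681 and 0.202). All 52 genes stayed called lower, with a median difference of -1.05 (quartiles -1.36 to -0.84) against -1.13 without weights. Both of these fits called more genes lower than the main fit, so genes already called there were likely to stay called. That they stayed called is therefore weak evidence. The size of the difference is weak evidence too, since the 52 genes were picked for it in the same libraries. The medians show only that neither adjustment removed the difference in these genes. With the length trend removed the median of the 52 genes was -1.11. Without each of the 3 libraries alone 39, 52 and 44 stayed called, with medians of -1.14, -1.10 and -1.10. Without all 3, which leaves 1 vehicle_Nutlin library, assumed to vary like the other groups, the median was -0.99. A larger Nutlin response of every gene cannot be measured on these genes, which were chosen for the difference, but lists not chosen for it argue against it: the added response in AG-120 cells was 2.73% (95% interval -2.27% to 7.74%) of the response in vehicle cells for p53 targets and 0.0206% (-4.45% to 4.49%) for G2/M genes. A biological effect of AG-120 stays open, and whether it acts here through 2-HG was not tested.

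The second pattern is the fall of ribosomal protein genes with AG-120 in Nutlin-treated cells, with a difference of list means of -0.55 (95% interval -0.89 to -0.22). Without vehicle_Nutlin replicate 3 it was -0.37 (-0.56 to -0.18), and with the length trend removed -0.39 (-0.59 to -0.19), so neither accounts for all of it, though each interval overlaps the first. Without the 3 libraries that stood apart it was -0.32 (-0.47 to -0.17), with 1 vehicle_Nutlin library left, so that this interval takes its spread from the other groups. How much of it is biological stays open.

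The third pattern is the rise of histone mRNAs with AG-120 without Nutlin. Carry-over of RNA without a poly(A) tail would raise them where RMRP, RPPH1 and RN7SK are raised, which stood at 23.5, 19.9 and 67.9 CPM in AG120 replicate 1 and at 8.38, 24.6 and 19.4 CPM in replicate 2, but at 0, 0.263 and 1.11 CPM in replicate 3. The histone mean (log2 CPM) was 2.42 and 2.13 in replicates 1 and 2 but 1.37 in replicate 3, against 0.88, 1.19 and 1.17 in vehicle, so the size of the rise went with these RNAs. In replicate 3, 7 of 10 members still lay above every vehicle library, against 9 and 10 in replicates 1 and 2. Libraries with Nutlin do not decide, since S phase genes were low there and most histone mRNAs without a tail are made in S phase, so with 1 AG120 library in which these RNAs were not raised, carry-over and a biological change cannot be told apart.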

How the results depend on the processing

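Leaving out 3 libraries, which leaves 1 vehicle_Nutlin library, assumed to vary like the other groups, removing the length trend and voom weights were chosen after the data were seen. No result reversed. Both Nutlin gene counts stayed within 1.5 times, their p53, G1/S and G2/M list calls held, and none of these lists was called in the difference, under each alternative run. The correlation of the Nutlin responses was 0.824 to 0.894 with libraries left out in turn. The 10 gene counts, 170 list results and 410 named-gene results were each counted once per alternative. So counted, gene counts were the same 96 times and moved 74 times. List results were the same 2212 times, lost a call 135 times and gained one 67 times. Named-gene results were the same 6344 times, lost a call 340 times and gained one 40 times. A change of sign without a call in either fit counted as the same. With library totals the median gene in the Nutlin response in vehicle cells was at -0.10, against -0.02 with TMM.

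AG-120 effect without Nutlin: genes higher, 8, became 85 with DESeq2, 73 with no filter, 4 with the replicate block, 24 with only both groups, 608 without the 3 libraries, 17 with the length trend removed, 601 with voom weights, and 1 to 9 leaving out each library. AG-120 effect without Nutlin: genes lower, 0, became 23 with DESeq2, 2 with library totals, 31 with no filter, 2 with 1 CPM in 3 libraries, 5 with only both groups, 300 without the 3 libraries, 3 with the length trend removed, 318 with voom weights, and 0 to 1 leaving out each library.

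AG-120 effect with Nutlin: genes higher, 68, became 263 with DESeq2, 594 with no filter, 33 with the replicate block, 0 with only both groups (edgeR), 629 without the 3 libraries, 376 with voom weights, and 5 to 418 leaving out each library. AG-120 effect with Nutlin: genes lower, 303, became 640, 678, 178, 15, 745 and 603 in the same settings, and 56 to 619 leaving out each library.

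The count for difference between the Nutlin responses: genes higher, 5, became 26 with DESeq2, 80 with no filter, 2 with the replicate block, 185 without the 3 libraries, 10 with the length trend removed, 75 with voom weights, and 1 to 36 leaving out each library. The count for difference between the Nutlin responses: genes lower, 52, became 197, 203, 30, 452, 81 and 358 in the same settings, and 22 to 207 leaving out each library. The labels do not say whether replicate numbers pair the samples. Deviations from the group mean correlated at -0.22 to 0.12 between libraries of the same number and at -0.19 to 0.21 between others. The block thus spends degrees of freedom on labels without a known meaning, but pairing was not excluded.

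The list call for p53 targets, all in AG-120 effect without Nutlin (0.004166) was lost with an estimated correlation (0.1444) and ranged from 6.159e-07 to 0.0735 leaving out each library. The call for p53 targets, all in AG-120 effect with Nutlin (0.004245) was lost likewise (0.2369) and ranged from 6.648e-06 to 0.1083. G1/S genes in AG-120 effect with Nutlin (0.01828) lost the call with an estimated correlation (0.2223) and voom weights (0.05803) and ranged from 0.003032 to 0.08248. G2/M genes in AG-120 effect with Nutlin (0.0001641) lost it with an estimated correlation (0.08637). Where no cause is named here, the cause was not tested. Depth was not varied: on simulated data with this depth and 3 libraries per group, 28% of 2-fold differences between the Nutlin responses were recovered with edgeR.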

Other observations

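Several lists that were not called as a whole held strong changes in both directions with Nutlin in vehicle cells. Of 28 ATF4 targets 10 rose and 14 fell, with NUPR1 at 4.38 and SLC7A5 at -2.84 (list adjusted p = 0.4492). Of 34 hypoxia and glycolysis genes 9 rose and 12 fell, with P4HA2 at 1.97 and HK2 at -1.65 (0.6501). Of 22 secretory inflammatory genes 5 rose and 8 fell, with the cytokine IL1B at 3.42 and IGFBP3 at -1.79 (0.5335). Unfolded protein genes counted 4 higher and 7 lower of 18 (0.297), with DNAJB9 at 1.66 and HSP90B1 at -1.20. Hepatocyte markers counted 4 and 4 of 15 (0.9137), with TTR at 3.57 and HNF4A at -1.66, and MAPK output genes 8 and 3 of 18 (0.1885), with FOSL1 at -1.32.

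Genes of 2-oxoglutarate dioxygenases, enzymes that 2-HG can inhibit, counted 11 higher and 6 lower of 33 with Nutlin in vehicle cells (0.3763), and 0 were called by edgeR in the difference (list adjusted p = 0.7482). The IDH and 2-HG metabolism list counted 6 higher and 8 lower of 17 (0.252), with ADHFE1 at 2.59 and LDHA at -1.83. Its AG-120 effect without Nutlin had a median of -0.03, a mean of 0.03 and an adjusted p of 0.5142. Housekeeping genes counted 8 and 8 of 25 with Nutlin in vehicle cells (0.6311), with HPRT1 at -1.51, ACTB at -1.41 and CHMP2A at 0.95, so these 3 were not stable under Nutlin here. Over all genes tested, 53.9% were called in this comparison.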
